A study of Mus musculus with 14 samples.

How the data were processed

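Deposited signal values of 14 Affymetrix arrays were used, in intensity units of MAS5 5.0 with global scaling, per the submitters' processing notes. Group, day, dose and replicate were taken per the labels. Each array held a pool of RNA from 3 mice, the 2 pools of a group are called independent biological replicates in the labels, and a p-value therefore speaks about pools of mice treated in 1 study. Image files were not analysed here, and detection calls are not given in the sources used here.

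The plan, written before the data were examined, assumed that all arrays shared the scale to which the authors had brought them. The 2%-trimmed mean was 150.04 on 11 arrays and 223.4, 300.3 and 334.6 on estradiol day 2 replicate 2 and estradiol day 3 replicates 1 and 2, which is 1.49, 2.00 and 2.23 times the common value. As a deviation from the plan all arrays were multiplied to a trimmed mean of 150.04, and the fit of the values as deposited was kept as an alternative. The reason for the other scale is not given in the sources used here.

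Of 22690 probe sets, 64 control probe sets were removed. A pseudocount of 16 was added and the log2 taken, and the lowest 40% by mean over all arrays were left out, blind to group. This left 13575 probe sets, with a lowest mean of 5.92 (a signal of 44.5), standing for 8214 genes, of which 2821 had more than 1 probe set. Of all probe sets 20393 carried 1 gene symbol, 691 several and 1606 none, and 20364 symbols were matched to the current gene table. Values were not averaged over probe sets. Where a gene is named it is represented by its probe set with the highest mean unless the text says otherwise, and probe sets with several symbols or none were counted but not named.

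limma 3.58.1 in R 4.3.3 fitted a mean for each of the 7 groups (lmFit), with contrasts for each day and for the equal mean of the 3 days, eBayes with an intensity trend and Benjamini-Hochberg adjustment within each comparison. A probe set was called at an adjusted p under 0.05. The fit had 7 residual degrees of freedom, or 13.74 after moderation. The comparisons were estradiol against control, genistein against control and estradiol against genistein, each at days 2, 3 and 6 and over the mean of days, and F tests of change over the days of estradiol, over the days of genistein and of the interaction of treatment and day. SE are those of limma, and SD are between arrays.

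Genes were named by a rule. In comparisons over the mean of days these were the 10 largest rises and 10 largest falls among genes that passed and whose arrays on one side all lay beyond all of the other side, at single days the 5 largest of each, and in F tests the 6 smallest p. Where none passed, the 5 smallest p were given as values. Esr1, Esr2, Pgr, Rag1, Cd4 and Cd8a were always looked up, and up to 4 members were named for a list that is described. Genes named outside the rule are said to be chosen after their values were seen.

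Lists of genes were written from general knowledge of cell types and pathways. They were tested with camera at its preset correlation of 0.01 where at least 5 genes were measured, which held for 34 of 37. Left out were red blood cells (2 genes measured), steroid-producing and pancreatic cells (2) and parathyroid and thyroid cells (3). Adjusted p for lists were taken over all lists of the 8 comparisons against control together, and of the 4 between treatments together. Each list was also tested with the correlation estimated from the data and with fry. No list passed with an estimated correlation.

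To test the procedure, 100 probe sets were shifted 2-fold and 100 others 4-fold on all estradiol arrays in values simulated from the real means and spread. For estradiol at day 6 it recovered 65 and 96 of 100, over the mean of days 80 and 100, and for estradiol against genistein over the mean of days 91 and 100, with 11, 13 and 11 false calls among 13575. A list of 20 genes shifted by 0.4 was recovered (camera adjusted p = 1.15e-21), and 0 of 33 other lists were called. Genes varied independently in these simulated values. The test therefore does not show how often camera's preset correlation calls lists of correlated genes that have not changed.

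Other settings chosen in advance were a pseudocount of 1 or 64, no filter, the lowest 60% left out, quantile normalization, centring on medians, eBayes without a trend, the replicate number as a block, only the groups compared, probe sets with _x_at or _s_at endings left out, each array left out in turn, the estimated correlation and fry. Alternatives chosen after seeing the data were the values as deposited, the 3 arrays at another scale left out, that scale as a block, and the ratio of 3' to 5' Gapdh signals as a covariate. The fold changes of the treatments were compared with 50 simulations in which both treatments had no effect and shared the control arrays. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.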

Results

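Thymus RNA was measured on 14 Affymetrix oligonucleotide arrays from female C57BL/6 mice, an inbred strain, that had been ovariectomised at 26 days of age and were treated from 30 days of age. The arrays formed 7 groups of 2. The control group was taken untreated at day 0. The remaining groups were taken on days 2, 3 and 6 of treatment. It was either daily subcutaneous injections of 125 ng of 17β-estradiol, the main ovarian estrogen, in 0.02 ml of corn oil, or a diet with 1500 ppm of genistein, a soy isoflavone that binds estrogen receptors. Each array held RNA pooled from 3 mice, and the labels describe the 2 pools of a group as independent biological replicates. The table held 22690 probe sets, of which 13575, standing for 8214 genes, were bright enough to be tested, and the number of arrays limits the precision. Untreated arrays of days 2, 3 or 6 were not analysed here, so in each comparison with control the treatment and the days since its start cannot be told apart. The labels list corn oil injections for the estradiol groups only. Effects of injection, oil and handling can therefore not be separated from those of the hormone, against control or against genistein.

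The deposited signals of 11 arrays shared a 2%-trimmed mean of 150.04, while those of estradiol day 2 replicate 2 and of estradiol day 3 replicates 1 and 2 were higher, at 223.4, 300.3 and 334.6. All arrays were brought to the common scale before they were compared. After this step control replicate 2 correlated least with the other arrays (mean r = 0.942 across probe sets) and stood farthest out on the first principal component, which held 20.6% of the variance. The second component, with 19.4%, set the estradiol day 3 and day 6 arrays apart from the rest. The ratio of 3' to 5' Gapdh signals, which rises as RNA breaks down, was 1.27 on estradiol day 2 replicate 1 and 1.503 on genistein day 6 replicate 1, against 0.867 to 1.10 elsewhere. The median SD between the 2 arrays of a group was 0.0842 log2 units at estradiol days 3 and 6, and 0.146 to 0.162 in the other groups.

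**Figure D1:**
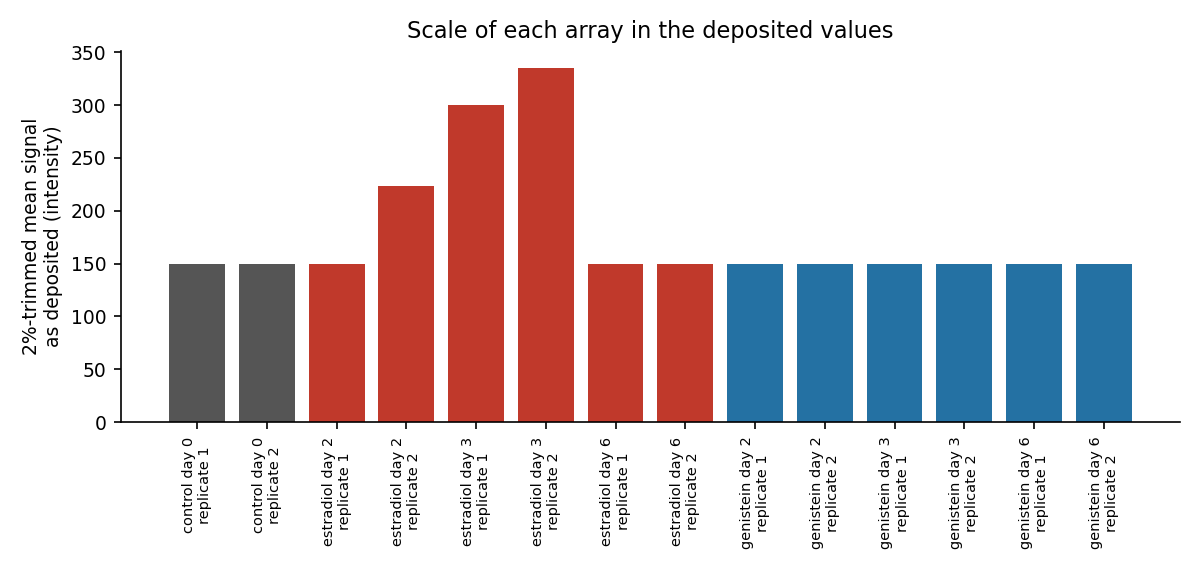
Trimmed mean signal of each of the 14 arrays as deposited (bars, intensity units, axis from 0), with the lowest and highest 2% of probe sets left out. The bars of 11 arrays stand at 150.04 and those of 3 estradiol arrays at 223.4, 300.3 and 334.6.

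Estradiol against untreated mice, averaged over the 3 days, addressed the mean change in the thymus over treatment, with the hormone, its injection and time combined. Slc2a4, the insulin-responsive glucose transporter, rose (log2 change 1.62 ± 0.157 SE, limma, adjusted p = 0.00046), from a signal of 13.5 ± 3.46 (SD, n = 2) in controls to 88.7 ± 8.20 at day 2. Its control signals lay below the pseudocount of 16, so the size of the change is approximate, at 2.40 with a pseudocount of 1 and 0.84 with 64. Cd7, a T cell surface glycoprotein, rose from a control signal as dim (10.1 ± 6.22) to 134 ± 4.67 at day 6, and Trgv1, a variable segment of the T cell receptor γ chain, rose 2.56-fold. Cyp51, Idi1, Fdps and Sqle, 4 enzymes of the cholesterol pathway, fell to 0.432, 0.484, 0.513 and 0.518 of their control levels. In all, 72 probe sets (60 genes) were higher and 10 (7 genes) lower at limma's adjusted p of 0.05, and 33 of them changed more than 2-fold.

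Cd7 had a log2 change of 2.12 ± 0.365 (limma, adjusted p = 0.0203), or 1.13 with a pseudocount of 64, so its size too is approximate. The nuclear noncoding RNA Malat1 rose by 1.96 ± 0.333 (limma, adjusted p = 0.0203). Its log2 levels were 7.26 and 7.06 in controls and 8.38 and 7.81 on the day 2 arrays. On those of days 3 and 6 they were 9.36 to 9.825. Malat1 has 4 other probe sets, with changes of 0.37, 0.72, 1.56 and 1.75 that did not pass. Fxr2, an RNA-binding relative of the fragile X protein, rose by 1.56 ± 0.303 and Scd1, which makes monounsaturated fatty acids, by 1.48 ± 0.274. Abcc3, an organic anion exporter that was also near the pseudocount in controls, rose by 1.27 ± 0.222 (1.98 with a pseudocount of 1 and 0.63 with 64), Alcam, an adhesion molecule and ligand of Cd6, by 1.18 ± 0.188, and Cysrt1 and Ccdc9 by 1.23 ± 0.252 and 1.18 ± 0.180. Trgv1 rose by 1.36 ± 0.184 (limma, adjusted p = 0.00524). Among the falls, Cyp51 fell by 1.21 ± 0.214, Idi1 by 1.05 ± 0.183, Fdps by 0.96 ± 0.133, Sqle by 0.95 ± 0.132 and the heat shock protein Hsph1 by 0.71 ± 0.139. Their limma adjusted p ran from 0.00524 to 0.0391. With a pseudocount of 64 the changes of Fxr2, Alcam, Ccdc9 and Cyp51 were 0.97, 0.78, 0.72 and -0.76. By the naming rule, each of these genes lay beyond both control arrays on all 6 estradiol arrays. Abcc3, Cysrt1 and Ccdc9 also lay above both controls on the genistein arrays, though without a call for genistein against control. Their signals were 51.3 to 79.1, 138 to 286.4 and 73.4 to 118.1 with genistein. With estradiol they were 47.3 to 76.8, 100.7 to 215.6 and 82.2 to 131. Of the genes named by the rule for this comparison, only Slc2a4 kept its call without control replicate 2. The calls of Fxr2, Cysrt1 and Hsph1 were lost without 7 or more of the 14 single arrays, each left out in turn. A second probe set of Klf9, a glucocorticoid-responsive transcription factor, chosen after its values were seen and dim in controls, rose by 2.30 ± 0.228 (limma, adjusted p = 0.00046), while the brighter Klf9 probe set changed by 0.55 ± 0.118 (adjusted p = 0.0597). Without control replicate 2 the count of 82 became 4, without control replicate 1 it became 560. Without estradiol day 3 replicate 1 or 2 or day 6 replicate 1 or 2 it became 34, 26, 28 and 27. It was 26 without the 3 arrays deposited at another scale, 14 with that scale as a term in the model and 38 with dim probe sets kept. On the deposited scale it was 4298, of which 4293 were higher against a median shift of all probe sets by 0.43.

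Of 34 gene lists, 17 passed camera as higher with estradiol and 3 as lower, and 0 passed with an estimated correlation. Markers of macrophages shifted up with estradiol (median log2 change 0.54 over 20 genes, 17 of them positive, camera adjusted p = 1.72e-09; adjusted p = 0.0529 with an estimated correlation). Of these, 4 rose among all genes tested, and 14 rose and 1 fell adjusted over the list alone. They included heme oxygenase Hmox1 (1.16 ± 0.175), the adhesion molecule Vcam1 (0.78 ± 0.112), Mertk, a receptor for dying cells (0.83 ± 0.170), and Csf1r, the macrophage growth factor receptor (0.55 ± 0.115). Hmox1 and Mertk stood at 0.71 and 0.52 with a pseudocount of 64. Mertk and Csf1r passed in only 9 of 27 and 9 of 28 alternative analyses and were lost without most single arrays, including arrays of genistein, which enter only the estimate of the spread. Of the 2 other Csf1r probe sets 1 went the same way and 0 passed. Thymic epithelial markers were positive for 19 of 19 genes (median 0.35, camera adjusted p = 1.95e-09; adjusted p = 0.0645 with an estimated correlation). Among them 4 rose over all genes and 11 adjusted over the list alone: Trp63 and Pax1, transcription factors of the epithelium, by 0.86 ± 0.145 and 0.87 ± 0.158, the chemokine Ccl25 by 0.50 ± 0.0961 and the protease Prss16 by 0.47 ± 0.0984. The Prss16 call, at an adjusted p of 0.0497, was likewise lost without most single arrays and held in only 9 of 28 alternative analyses. Adipocyte markers were positive for 11 of 11 genes (median 0.56, camera adjusted p = 9.61e-07; adjusted p = 0.153 with an estimated correlation), where 3 rose over all genes and 6 adjusted over the list alone. Lipoprotein lipase Lpl rose by 1.03 ± 0.150 and Cebpa, a transcription factor of fat cells, by 1.07 ± 0.195, besides Scd1. Fibroblast and matrix genes had a median of 0.29 (camera adjusted p = 2.56e-05; adjusted p = 0.127 with an estimated correlation). Over all genes limma gave 0 calls, although 9 of the 19 passed an unadjusted p of 0.05, and 8 were higher adjusted over the list alone. Col1a1 and Igfbp7 stood at 0.87 ± 0.198 and 0.78 ± 0.182 (limma, adjusted p = 0.0668 and 0.0701). The other Col1a1 probe set did not go the same way and did not pass.

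Endothelial markers had a median of 0.10 over 10 genes (camera adjusted p = 0.564), B and plasma cell markers 0.03 over 12 (adjusted p = 0.173) and double-positive thymocyte markers, the bulk of the organ, -0.05 over 16 (adjusted p = 0.322). Early thymocyte genes had a median of 0.29 (camera adjusted p = 0.000241, and adjusted p = 0.150 with an estimated correlation), with 0 limma calls over all genes and 3 higher adjusted over the list alone. Il7r, the interleukin 7 receptor, stood at 0.53 ± 0.126 and Il2ra, a marker of early stages, at 0.83 ± 0.225, neither of which passed. A second, dimmer probe set of Il2ra did pass and is described under other observations. Rag1, the recombinase of receptor assembly, differed by 0.01 ± 0.130, Cd4 by 0.20 ± 0.212 and Cd8a by -0.06 ± 0.103 (limma, adjusted p = 0.980, 0.703 and 0.828), and all 3 were bright, with mean signals of 2401, 807 and 1836. Since every array was brought to the common scale, these genes and the double-positive list give relative levels. They do not show whether the number of thymocytes changed. The estrogen receptor genes Esr1 and Esr2 and the progesterone receptor gene Pgr were too dim to be tested, with mean signals of 15.5, 14.2 and 19.2.

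Cell division genes shifted down with estradiol. The mitosis list was negative for 26 of 27 genes (median -0.27, camera adjusted p = 2.50e-08; adjusted p = 0.164 with an estimated correlation) and the DNA replication list for 24 of 27 (median -0.21, camera adjusted p = 8.08e-05; adjusted p = 0.0781 with an estimated correlation). Neither list had a limma call over all genes, and 7 and 2 genes were lower adjusted over the list alone. The mitotic kinases Aurka and Cdk1 stood at -0.49 ± 0.131 and -0.41 ± 0.114 (limma, adjusted p = 0.105 and 0.120). Cholesterol synthesis genes had a median of -0.35 over 15 (camera adjusted p = 1.74e-07; adjusted p = 0.0529 with an estimated correlation), with 4 that fell over all genes and 7 adjusted over the list alone. Glucocorticoid-responsive genes were positive for 17 of 17 (median 0.40, camera adjusted p = 1.95e-09; adjusted p = 0.0529 with an estimated correlation), with 3 higher over all genes and 10 adjusted over the list alone. Tsc22d3, the glucocorticoid-induced leucine zipper, rose by 1.03 ± 0.161, the extracellular peroxidase Gpx3 by 0.70 ± 0.142 and the metallothionein Mt2 by 0.78 ± 0.163. The 2 other Tsc22d3 probe sets stood at 0.63 and -0.16 without passing, and the Mt2 call was lost without most single arrays. Estrogen-responsive genes had a median of 0.26 over 19 (camera adjusted p = 7.80e-05; adjusted p = 0.0781 with an estimated correlation), of which Cyp1b1, an estrogen hydroxylase, rose over all genes (0.81 ± 0.163, limma, adjusted p = 0.0426, lost without most single arrays) and 7 rose adjusted over the list alone. MHC class II genes had a median of 0.37 over 9 (camera adjusted p = 0.000299; adjusted p = 0.129 with an estimated correlation), with H2-Ab1 up by 0.55 ± 0.106 over all genes, and 6 higher and 1 lower adjusted over the list alone. Oxidative stress genes had a median of 0.29 over 19 (camera adjusted p = 1.79e-05; adjusted p = 0.0834 with an estimated correlation), where the 4 that rose over all genes were Hmox1, Cyp1b1, Gpx3 and Mt2, and 6 rose adjusted over the list alone.

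**Figure D2:**
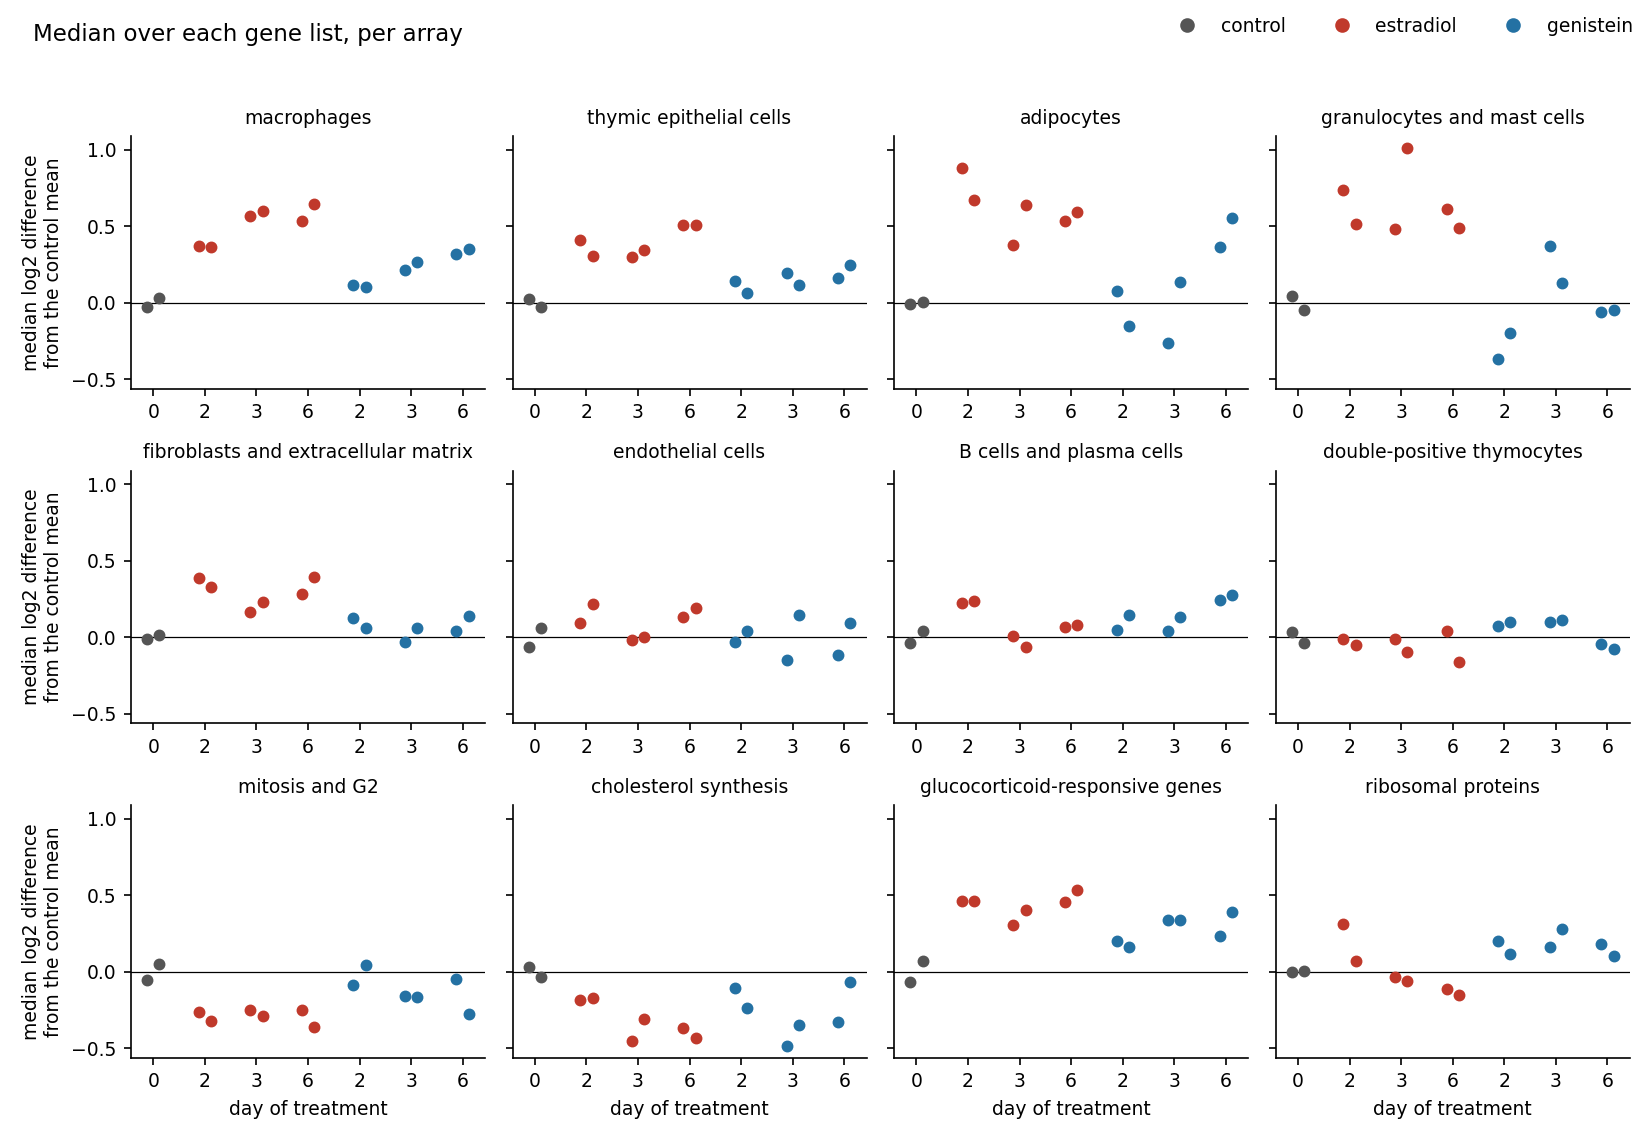
Median log2 difference from the control mean (vertical axis) over the genes of 12 lists, for each array (points), by day of treatment and coloured by group. Macrophage, epithelial and adipocyte medians lie above 0 on all 6 estradiol arrays, and the lists' median changes with estradiol were 0.54, 0.35 and 0.56.

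By day 2 of estradiol the largest named rises were Slc2a4 (1.83 ± 0.193, limma, adjusted p = 0.00276), the resistin-like protein Retnla (1.33 ± 0.205), Lpl (1.18 ± 0.183) and the carbonyl reductase Cbr2 (1.09 ± 0.138). Fdps and Sqle had already fallen by 0.97 ± 0.162 and 0.96 ± 0.161. At day 3 Malat1 rose by 2.64 ± 0.408, Slc2a4 by 1.57 ± 0.193, Hmox1 by 1.30 ± 0.214 and Cbr2 by 0.95 ± 0.138, and Fdps fell by 1.08 ± 0.162. At day 6 Cd7 rose by 2.54 ± 0.447, Malat1 by 2.31 ± 0.408, Fxr2 by 1.97 ± 0.372, Trgv1 by 1.74 ± 0.225 and Iglv1, an immunoglobulin light chain segment, by 1.72 ± 0.209. Sqle, Fdps and the tubulin Tuba1a fell by 0.96 ± 0.161, 0.84 ± 0.162 and 0.70 ± 0.146. With a pseudocount of 64 Slc2a4 stood at 0.98 and 0.80 at days 2 and 3, Hmox1 at 0.81 at day 3, and Cd7 and Fxr2 at 1.42 and 1.26 at day 6. Lost without 7 or more of the single arrays were the calls of Fdps and Sqle at day 2, of Malat1, Hmox1 and Fdps at day 3 and of Tuba1a at day 6. The counts of higher and lower probe sets were 10 and 2 at day 2, 8 and 1 at day 3, and 83 and 6 at day 6 (limma, adjusted p of 0.05). Without control replicate 1 those days' counts were 312, 184 and 367. Without control replicate 2 they were 1, 0 and 17. Without estradiol day 2 replicate 1 day 2 had 6, of which 3 were higher and 3 lower, and without the 3 arrays deposited at another scale it had 4, of which 1 was higher and 3 lower. Without either day 3 array day 3 had 0, and without day 6 replicate 1 or 2 day 6 had 13 and 0. Arrays of groups that were not compared enter only the estimate of the spread. Without estradiol day 6 replicate 1 or 2 day 2 had 7 calls and day 3 had 3. Without genistein day 6 replicates 1 and 2 day 2 had 20 and 19 and day 3 had 14 each. Without either estradiol day 2 array or either genistein day 2 array day 3 had 5, and without either estradiol day 3 array day 6 had 53.

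The macrophage list was shifted up on each day (medians 0.41, 0.58 and 0.60 at days 2, 3 and 6) and the cholesterol list down (-0.19, -0.45 and -0.35). Camera's adjusted p was at most 3.19e-07 for the first and 2.36e-05 for the second, and with an estimated correlation the adjusted p were 0.0597, 0.0529 and 0.0529 for macrophages and 0.0588, 0.0529 and 0.0645 for cholesterol synthesis. Among all genes 0, 1 and 4 macrophage genes rose at days 2, 3 and 6, and adjusted over the list alone 10, 13 and 14 rose while 1 fell at day 3. Of the cholesterol genes 2, 1 and 2 fell among all genes and 6, 8 and 7 adjusted over the list alone. A test of whether levels differed among the 3 days of estradiol called 3 probe sets (limma's moderated F test). They were Plvap, a protein of endothelial diaphragms (adjusted p = 0.00968), a minor probe set of Nktr, a cyclophilin-related protein of natural killer cells (adjusted p = 0.0348), and a minor probe set of Ighm, the IgM heavy chain (adjusted p = 0.00968). Plvap had log2 levels of 6.999 at day 2, 5.49 at day 3 and 6.89 at day 6, against 6.40 in controls. The next smallest p among genes represented by their brightest probe sets belonged to Iglv1 (limma, adjusted p = 0.0597), with Tmem37, Vipas39, the joining chain Jchain and the lysosomal protease Ctss between 0.167 and 0.272. Without estradiol day 3 replicate 1 or 2 or day 6 replicate 2 no probe set passed. Without day 2 replicate 2 there were 8, without either genistein day 3 array 5, and without the 3 arrays deposited at another scale 0.

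Genistein against untreated mice, averaged over days, addressed what differed from day 0 on the isoflavone diet, with the diet and time combined. Slc2a4 rose (log2 change 1.59 ± 0.157, limma, adjusted p = 0.00133, or 2.36 with a pseudocount of 1 and 0.82 with 64, since controls lay below it), with signals of 67.5 ± 4.46, 71.9 ± 12.3 and 78.4 ± 1.49 (SD, n = 2) at days 2, 3 and 6 against 13.5 ± 3.46 in controls. Tsc22d3 rose 2.10-fold (1.07 ± 0.161, adjusted p = 0.0412), and the second probe set of Klf9 rose by 1.73 ± 0.228 (adjusted p = 0.0190). Hsph1 fell by 0.97 ± 0.139 (adjusted p = 0.0312) and C77080 by 0.97 ± 0.150 (adjusted p = 0.0446). The calls of Tsc22d3, Hsph1 and C77080 were lost without most single arrays, and the 2 other Tsc22d3 probe sets stood at 0.60 and -0.06 without passing. These 5 probe sets, 3 higher and 2 lower, were all that passed limma's adjusted p of 0.05, while 1507 passed an unadjusted p of 0.05. At single days Slc2a4 rose by 1.51 ± 0.193, 1.58 ± 0.193 and 1.69 ± 0.193 (limma, adjusted p = 0.0137, 0.0164 and 0.00752), and at day 2 C77080 fell by 1.45 ± 0.183 (adjusted p = 0.0137), with no other call on any day. With a pseudocount of 64 C77080 stood at -0.62 over the mean of days and -0.90 at day 2, and Slc2a4 at 0.76, 0.81 and 0.88 at days 2, 3 and 6. Rag1 differed by -0.00 ± 0.130, Cd4 by 0.14 ± 0.212 and Cd8a by 0.06 ± 0.103, and none passed.

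Leaving out control replicate 1 raised the genistein counts to 335 over the mean of days and to 287, 101 and 151 at days 2, 3 and 6. Without control replicate 2 they were 1, 0, 0 and 1. The count over the mean of days was 1 without genistein day 3 replicate 2, 2 without either genistein day 2 or day 6 array or any estradiol day 3 or day 6 array, 0 with the lowest 60% of probe sets left out and 1 with dim probe sets kept. At day 2 the count was 0 and 7 (1 higher, 6 lower) without genistein replicates 1 and 2 and 6 (2 higher, 4 lower) without estradiol day 2 replicate 2, and Slc2a4 did not pass without either genistein array. At day 3 it was 2 and 0 without genistein replicates 1 and 2 and 0 without either estradiol day 3 array. At day 6 it was 0 without genistein replicate 2, and without replicate 1 the only call was a lower one, so Slc2a4 did not pass in either case. In each of these other settings in which Slc2a4 was tested, its change over the mean of days passed.

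Of 34 gene lists, 8 passed camera as higher with genistein and 4 as lower, and 0 passed with an estimated correlation. Cholesterol synthesis genes were negative for 12 of 15 (median -0.19, camera adjusted p = 3.19e-06; adjusted p = 0.0591 with an estimated correlation), with 0 limma calls over all genes and 6 lower adjusted over the list alone. Cyp51, Idi1 and Sqle stood at -0.91 ± 0.214, -0.82 ± 0.183 and -0.59 ± 0.132 (limma, adjusted p = 0.237, 0.236 and 0.236). Heat shock genes had a median of -0.10 over 23 (camera adjusted p = 0.000191; adjusted p = 0.0979 with an estimated correlation), in which Hsph1 fell over all genes and 3 fell adjusted over the list alone. The chaperones Dnaja1 and Hsp90b1 stood at -0.62 ± 0.141 and -0.39 ± 0.113 without passing. Glucocorticoid-responsive genes were positive for 17 of 17 (median 0.23, camera adjusted p = 1.59e-05; adjusted p = 0.0797 with an estimated correlation), with Tsc22d3 higher over all genes and 4 higher adjusted over the list alone, and Gpx3 and Il7r at 0.58 ± 0.142 and 0.52 ± 0.126. Ribosomal protein genes had a median of 0.18 over 19 (camera adjusted p = 2.68e-05; adjusted p = 0.263 with an estimated correlation), with 0 limma calls over all genes and 1 adjusted over the list alone, and after quantile normalization the median was -0.01. Rps6 stood at 0.63 ± 0.147. Macrophage genes had a median of 0.24 over 20 (camera adjusted p = 0.000608; adjusted p = 0.121 with an estimated correlation), with 0 limma calls over all genes or over the list alone. Without control replicate 1 camera's adjusted p was 0.0996 for the macrophage list and 0.0620 for the heat shock list. C1qa, a subunit of complement, and Cd68, a lysosomal glycoprotein, stood at 0.50 ± 0.152 and 0.38 ± 0.122. Epithelial markers had a median of 0.21 (camera adjusted p = 0.0214, and adjusted p = 0.326 with an estimated correlation). Adipocyte markers (0.14, camera adjusted p = 0.703) and granulocyte markers (-0.06, against a mean of 0.02, camera adjusted p = 0.977) did not pass. The adipocyte medians were 0.0739 and -0.149 on the 2 arrays of day 2 and -0.2645 and 0.133 on those of day 3. On those of day 6 they were 0.362 and 0.554, and a change over days was not tested for the list. Levels did not differ among the 3 days of genistein in limma's F test for any probe set (smallest adjusted p = 0.587), although 786 passed an unadjusted p of 0.05, led by Cbr2, at 9.29, 9.91 and 10.1 on days 2, 3 and 6, and C77080, at 5.58, 6.66 and 5.95. Without genistein day 2 replicate 2 there were 2 calls and without day 6 replicate 1 there was 1.

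**Figure D3:**
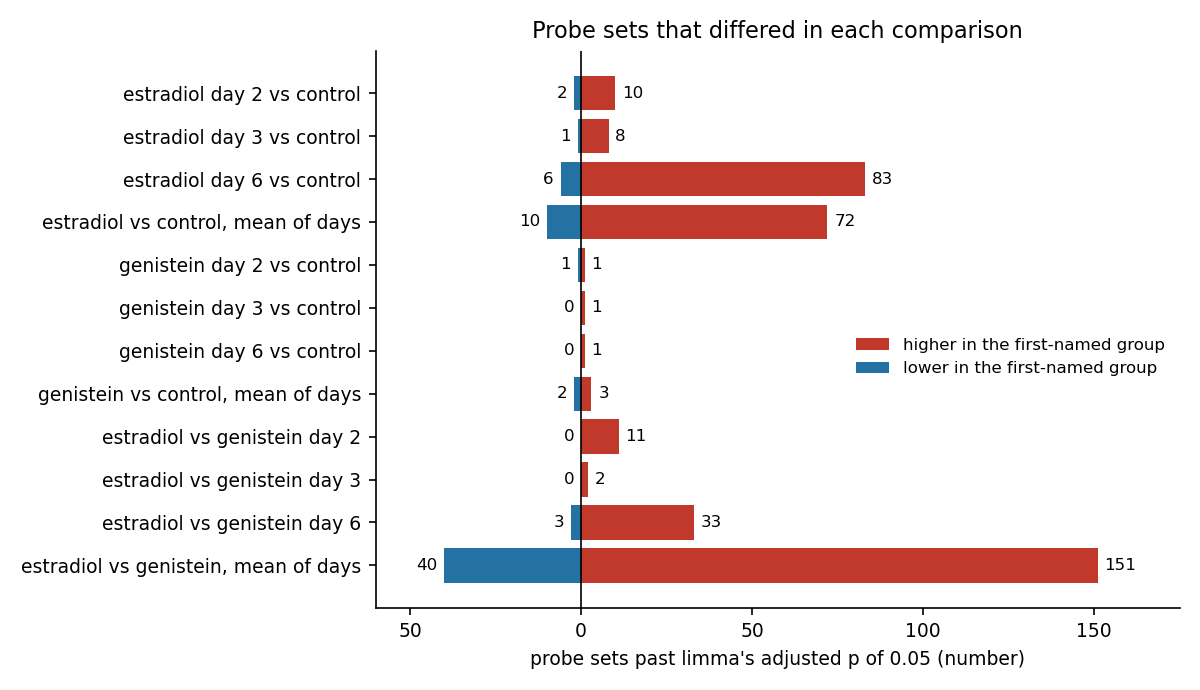
Number of probe sets higher (right of 0) and lower (left of 0) at limma's adjusted p of 0.05 in each comparison. Estradiol against genistein over the mean of days has the most, 151 higher and 40 lower, and genistein against control 3 and 2.

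Estradiol against genistein compared the treatments on the same days, with different routes and doses, over 6 arrays each. Ngp, a granule protein of neutrophils, was 2.05-fold higher with estradiol, and S100a9 and S100a8, the subunits of calprotectin, 1.97-fold and 1.94-fold. Fabp4, the fatty acid carrier of adipocytes, was 1.78-fold and Scd1 2.53-fold higher. Trgv1 was 2.23-fold higher, and Ly75, an endocytic receptor of dendritic and epithelial cells, 1.77-fold. Lower with estradiol were Cd8b1, the β chain of the T cell coreceptor, at 0.821 of its genistein level and Oaz1, the antizyme of polyamine synthesis, at 0.805. In all, 151 probe sets (128 genes) were higher and 40 (28 genes) lower, and 20 of these probe sets differed by more than 2-fold. The lower count ranged from 3 to 95 with 1 array left out.

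Trgv1 differed by 1.16 ± 0.130 (limma, adjusted p = 0.000845), Ngp by 1.04 ± 0.144, S100a9 by 0.98 ± 0.136 and Fabp4 by 0.83 ± 0.116 (each with adjusted p = 0.00297). Igfbp7, a secreted binding protein of growth factors, differed by 0.88 ± 0.129, Cmah, which makes a sialic acid, by 0.87 ± 0.120, the scaffold protein Ahnak by 0.85 ± 0.143, Ly75 by 0.82 ± 0.173, Ufsp1 by 0.80 ± 0.104 and Alcam by 0.77 ± 0.133, with limma adjusted p from 0.00190 to 0.0350. Oaz1 and Cd8b1 differed by -0.31 ± 0.0615 and -0.28 ± 0.0594 (limma, adjusted p = 0.0246 and 0.0345). By the naming rule, every array of either treatment lay beyond all 6 of the other for these 12 genes. Slc2a4, high with both, was 6.50 ± 0.212 with estradiol and 6.46 ± 0.126 with genistein (mean log2 level ± SD, n = 6). Rag1, Cd4 and Cd8a differed by 0.01 ± 0.0922, 0.06 ± 0.150 and -0.12 ± 0.0731, and none passed. The calls of Ly75, Oaz1 and Cd8b1 were lost without 7 or more of the single arrays. Leaving out estradiol day 2 replicate 1 gave 163 higher and 95 lower calls. Without estradiol day 3 replicate 1 or 2 or day 6 replicate 1 or 2 there were 65, 63, 69 and 62, of which 3, 6, 4 and 8 were lower. Leaving out genistein day 2 replicate 1, day 3 replicate 2 or day 6 replicate 1 or 2 gave 98, 76, 82 and 321, of which 15, 5, 9 and 82 were lower. The count was 41 without the 3 arrays deposited at another scale, 32 with that scale as a term, 125 with dim probe sets kept and 158 (106 higher, 52 lower) with arrays centred on their medians. On the deposited scale it was 9262 (9260 higher), where the median shift was 0.42 and Oaz1 and Cd8b1 turned to 0.14 and 0.17.

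Of 34 gene lists, 16 passed camera as higher with estradiol than with genistein and 5 as lower, and 0 passed with an estimated correlation. Adipocyte markers had a median of 0.65 over 11 genes (camera adjusted p = 5.89e-09, and adjusted p = 0.110 with an estimated correlation), with 5 higher over all genes and 9 adjusted over the list alone. The gap was wide at day 2, with medians from the control mean of 0.883 and 0.669 on the estradiol arrays and 0.0739 and -0.149 on the genistein arrays. At day 3 the medians were 0.377 and 0.638 against -0.2645 and 0.133. The gap was small at day 6, with 0.536 and 0.592 against 0.362 and 0.554. Whether it changed over the days was not tested for the list. Lpl differed by 0.70 ± 0.106, Scd1 by 1.34 ± 0.194 and the brown fat uncoupling protein Ucp1 by 1.82 ± 0.405, with Ucp1 spread by an SD of 1.33 log2 units among the estradiol arrays and a difference of 1.12 with a pseudocount of 64. The Ucp1 call was lost without most single arrays and held in 7 of 27 alternative analyses. Epithelial markers were higher for 18 of 19 genes (median 0.23, camera adjusted p = 1.05e-08; adjusted p = 0.110 with an estimated correlation), with 5 passing over all genes and 10 adjusted over the list alone, among them Tbata (0.49 ± 0.0746), Trp63 (0.62 ± 0.102) and Pax1 (0.64 ± 0.112). Macrophage markers had a median of 0.22 over 20 (camera adjusted p = 1.99e-07; adjusted p = 0.110 with an estimated correlation), 4 passing over all genes and 10 adjusted over the list alone: Vcam1 differed by 0.49 ± 0.0792, Hmox1 by 0.73 ± 0.123, Mertk by 0.53 ± 0.120 and the mannose receptor Mrc1 by 0.44 ± 0.101. Hmox1 and Mertk differed by 0.47 and 0.34 with a pseudocount of 64. Mertk and Mrc1 held in only 7 of 27 and 6 of 28 alternative analyses, and Mrc1 was lost without any of the 12 treated arrays in turn and Mertk without most. Granulocyte markers had a median of 0.72 over 6 (camera adjusted p = 4.01e-05; adjusted p = 0.110 with an estimated correlation), with Ngp, S100a9 and S100a8 passing over all genes, 4 higher and 1 lower adjusted over the list alone, and lactoferrin Ltf at 0.49 ± 0.116 (limma, adjusted p = 0.0575). Fibroblast and matrix genes had a median of 0.20 over 19 (camera adjusted p = 3.98e-06; adjusted p = 0.118 with an estimated correlation), with 3 passing over all genes, Igfbp7, fibronectin Fn1 (0.55 ± 0.0959) and decorin Dcn (0.56 ± 0.123), and 7 adjusted over the list alone. The Dcn call was lost without most single arrays. Endothelial markers had a median of 0.01 (camera adjusted p = 0.432).

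Estrogen-responsive genes were higher with estradiol than with genistein for 17 of 19 (median 0.19, camera adjusted p = 0.000196; adjusted p = 0.110 with an estimated correlation). Lipocalin Lcn2 (0.63 ± 0.129, or 0.39 with a pseudocount of 64) and Cyp1b1 (0.50 ± 0.115) passed over all genes and 6 adjusted over the list alone. Both calls were lost without most single arrays, and Cyp1b1, at an adjusted p of 0.0497, held in only 5 of 27 alternative analyses. Ribosomal protein genes were lower for 19 of 19 (median -0.21, camera adjusted p = 4.37e-08; adjusted p = 0.176 with an estimated correlation), with Rps6 at -0.48 ± 0.104 passing over all genes, a call lost without most single arrays, and 10 adjusted over the list alone. After quantile normalization camera's adjusted p for them was 0.606, and with the deposited scale as a term it was 0.229. On the deposited scale Rps4x and Rpl8, at -0.23 and -0.24 here, turned to 0.22 and 0.21. Mitosis genes were lower for 24 of 27 (median -0.15, camera adjusted p = 7.34e-06; adjusted p = 0.210 with an estimated correlation), with 0 limma calls over all genes and 8 adjusted over the list alone, and Aurka and Cdk1 at -0.38 ± 0.0924 and -0.33 ± 0.0806. Cholesterol synthesis genes were lower for 11 of 15 (median -0.19, camera adjusted p = 0.0222; adjusted p = 0.176 with an estimated correlation), with Fdps passing over all genes and 2 adjusted over the list alone.

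**Figure D4:**
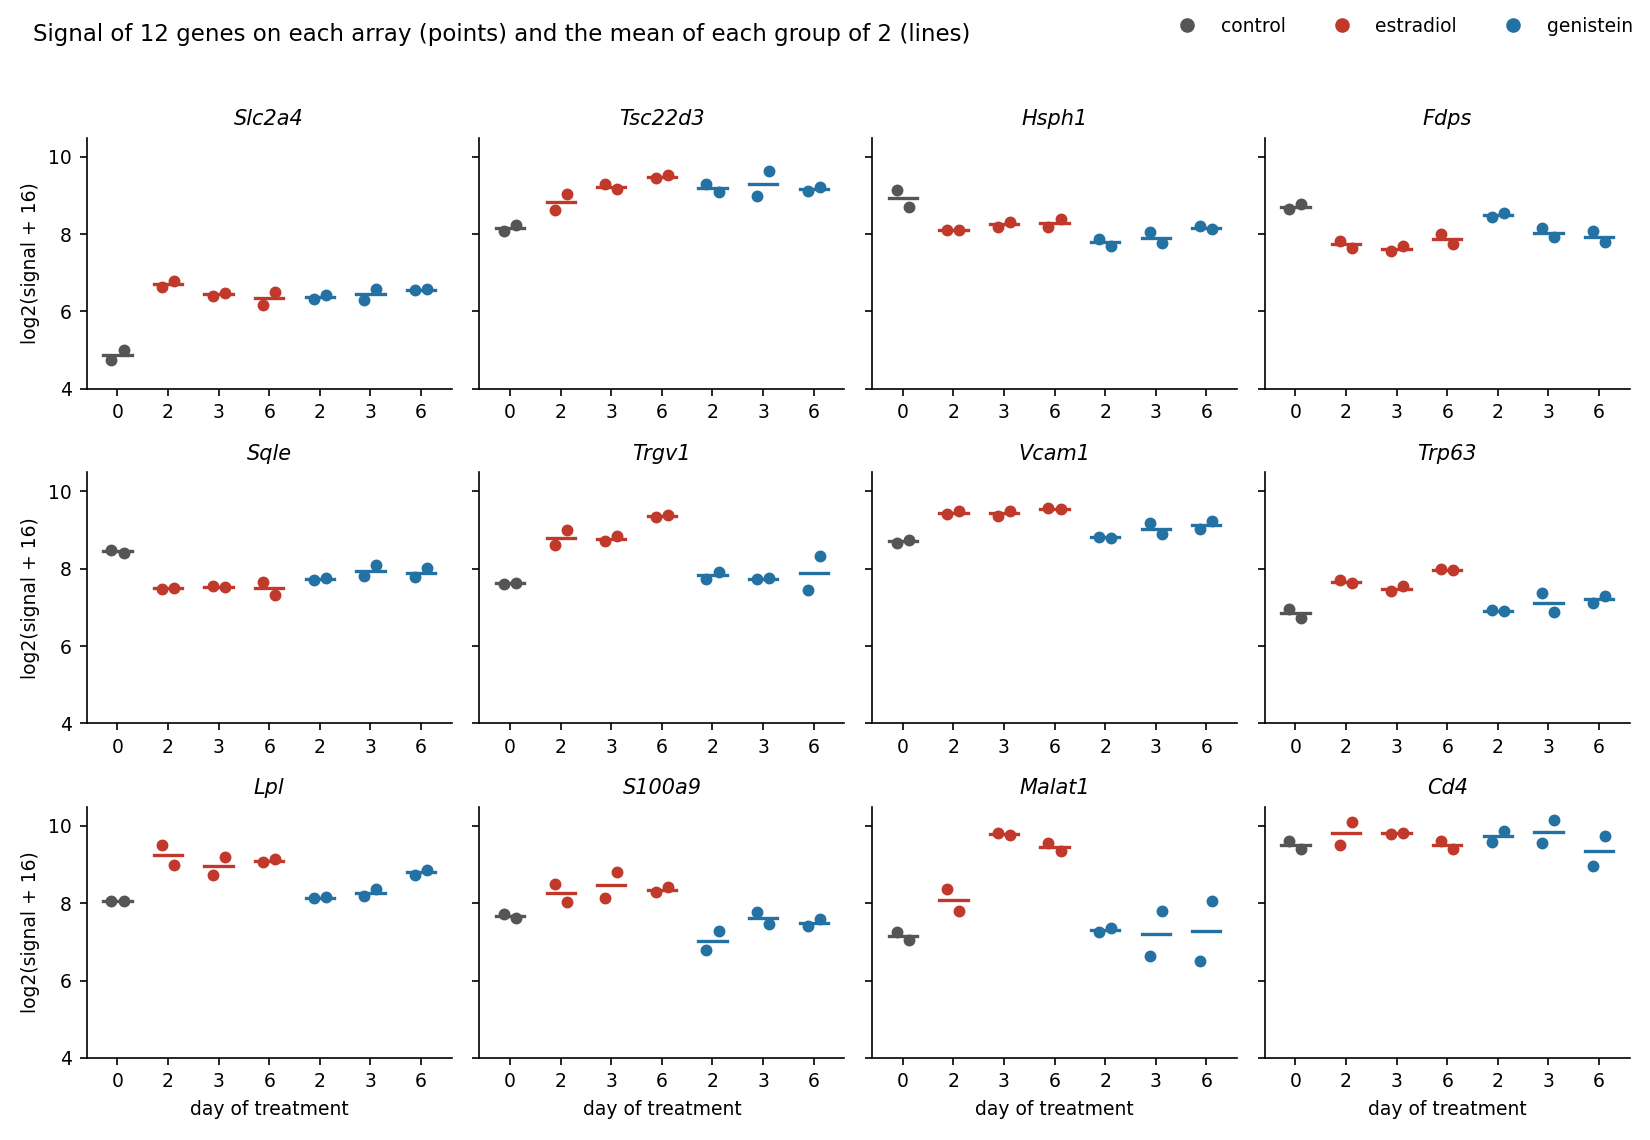
Signal of 12 genes on each array (points, log2 of signal plus 16) and the mean of each group of 2 (lines), by day of treatment. Slc2a4 has a control mean of 4.88 and means of 6.50 with estradiol and 6.46 with genistein over their 6 arrays, and Trgv1 has means of 7.63, 8.98 and 7.82.

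At day 2 estradiol stood above genistein for Lifr, the receptor of leukemia inhibitory factor, by 1.71 ± 0.258, Retnla by 1.64 ± 0.205, S100a8 by 1.59 ± 0.253, C77080 by 1.32 ± 0.183 and Lpl by 1.10 ± 0.183 (limma, adjusted p from 0.0104 to 0.0427). At day 3 the 2 probe sets that passed were a minor probe set of Nktr (1.81, limma, adjusted p = 0.00559), chosen after its values were seen, and 1 without a single gene name. Of genes represented by their brightest probe sets, Malat1, Ctss, Cmah, Gm6958 and Tent5c had the smallest p, with differences of 2.58 ± 0.408, -0.73 ± 0.132, 1.11 ± 0.207, 1.00 ± 0.192 and 0.95 ± 0.203 and limma adjusted p of 0.0933 to 0.249. At day 6 Malat1 was higher by 2.18 ± 0.408, Shisa2 by 1.47 ± 0.262, Trgv1 by 1.47 ± 0.225, Lifr by 1.45 ± 0.258 and Iglv1 by 1.44 ± 0.209, and Igha, the IgA heavy chain, was lower at -1.43 ± 0.263 (limma, adjusted p from 0.0132 to 0.0450). C77080 at day 2 and Shisa2 at day 6 stood at 0.81 and 0.88 with a pseudocount of 64. Lost when 7 or more of the single arrays were left out in turn were the calls of S100a8 and Lpl at day 2 and of Malat1, Shisa2, Lifr and Igha at day 6. The counts were 11 higher and 0 lower at day 2, 2 and 0 at day 3, and 33 and 3 at day 6, with 912, 910 and 1824 probe sets at an unadjusted p of 0.05. Day 2 had 1 call, a lower one, without estradiol day 2 replicate 1, so that none of its 5 named genes passed, 1 without genistein day 2 replicate 1 and 5 without either estradiol day 6 array. Day 3 had 0 without any of the 4 arrays compared, 6 without either genistein day 6 array and 1 without any of the other 8. Day 6 had 0 without either estradiol day 6 array, 4 and 67 without genistein day 6 replicates 1 and 2, 16 without either estradiol day 3 array, 19 without any day 2 array or either genistein day 3 array, and 0 with the Gapdh ratio as a covariate.

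Whether the difference between the treatments itself changed over the days was tested directly. No probe set passed limma's F test for the interaction of treatment and day, although 575 passed an unadjusted p of 0.05. The smallest adjusted p, 0.0601, was that of Plvap, whose estradiol and genistein levels were 6.999 and 5.95 at day 2, 5.49 and 6.35 at day 3 and 6.89 and 5.92 at day 6. Ctss followed (limma, adjusted p = 0.317), with 9.90 and 9.38, 9.16 and 9.89, and 9.58 and 9.76, and then Gm6958, Gtpbp6, Pik3r2 and D030056L22Rik (adjusted p from 0.517 to 1). Without genistein day 6 replicate 1 there was 1 call.

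The genes that moved with either treatment were set side by side. Slc2a4, Tsc22d3 and the dim second probe set of Klf9 were higher with both treatments, where independent lists of these sizes would share 0.0159, and Hsph1 was lower with both, against 0.00147. Simulations in which neither treatment had an effect and both shared the controls gave a mean of 0.02 shared calls in the same direction. With no effect few probe sets are called at all, so this value does not give the overlap to be expected beside the calls of estradiol. The calls of Tsc22d3 and Hsph1 with genistein were lost without control replicate 2 and without most other single arrays. Of the 2 other Tsc22d3 probe sets 1 went the same way with each treatment and 0 passed. Both comparisons used the same 2 control arrays, which cannot be split into groups of 2, so part of this excess may come from the shared controls. The days since day 0 were also common to both treatments and may add to it. Across the 13575 probe sets, which are not independent, the log2 changes of the treatments had a Pearson r of 0.706 and a Spearman rho of 0.687, and unchanged groups simulated against the same controls gave 0.749 and 0.727. The covariance was 0.0465 against a simulated 0.0233. At days 2, 3 and 6 r was 0.652, 0.589 and 0.488, where the simulations gave 0.4997, 0.499 and 0.498. Of the 82 probe sets called with estradiol over the mean of days, 78 had the same sign with genistein. Of the 82, 77 changed more with estradiol, and 47 passed between the treatments in its direction. The median over those that rose was 0.88 with estradiol and 0.29 with genistein, and over those that fell -0.81 and -0.70. They were picked by their estradiol change, which favours a larger change with estradiol, and the shared controls favour the same sign.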

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

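The tests of chance and of nuclear RNA were written down before their results were seen, and the other tests below were chosen only after the result was seen.

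The levels of 3 probe sets differed among the 3 days of estradiol in limma's F test. Plvap, a protein of endothelial diaphragms (adjusted p = 0.00968), stood at 0.60, -0.91 and 0.49 against control on days 2, 3 and 6 (SE 0.184 each), and at -0.45, -0.05 and -0.48 with genistein. A minor probe set of Nktr (adjusted p = 0.0348) stood at 0.32, 1.82 and 1.55 (SE 0.202), and at 0.03, 0.01 and -0.05 with genistein. A minor probe set of Ighm, the IgM heavy chain (adjusted p = 0.00968), stood at 1.39, 0.03 and 1.99 (SE 0.207), and at 0.13, -0.14 and 0.45 with genistein. Ighm had 4 other probe sets and Nktr 1. Both day 3 arrays of estradiol were among the 3 deposited at another scale, so for the day 3 levels of Plvap and Ighm the day and the scale cannot be told apart. For Nktr the log2 level at day 6, with both arrays on the common scale, was 7.263 ± 0.24 against 6.036 ± 0.195 at day 2 (SD, n = 2), a difference that the day 3 arrays do not enter, although 1 of the day 2 arrays was off scale. The day 3 and day 6 arrays of estradiol, where Nktr was high, also stood apart on the second principal component. Whether they shared a batch was not tested.

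For the probe sets called between estradiol and genistein over the mean of days, chance was tested by dividing the 12 treated arrays into groups of 6 in 100 ways. Fitted by treatment alone, the real division called 117 probe sets and the highest other 6, so only 1 of 100, the real one, reached that count. An arbitrary division of these arrays thus seldom gave such a count. The other divisions also placed any real difference between the treatments in the spread, which lowers their counts. All 3 arrays deposited at another scale were of estradiol, and the count over the mean of days fell without them. The splits therefore cannot tell the treatment from what else differed between the arms, and no conclusion on the cause is drawn.

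Markers of macrophages, epithelium and fat were higher with estradiol by camera at its preset correlation, but with an estimated correlation the adjusted p were 0.0529, 0.0645 and 0.153. A lower share of thymocytes could raise the markers of every other cell type alike. The macrophage median exceeded the endothelial one by 0.443 (permutation p = 0.0228 over genes). That test treats genes of the same arrays as independent, and the comparison was chosen after the result was seen. Dendritic cell, fibroblast and granulocyte medians rose too (0.295, 0.288 and 0.67), while B cell and striated muscle medians stood at 0.0293 and -0.12. The lists thus rose unequally, but a lower share of thymocytes is not excluded. Epithelium and fat were not compared in this way. The lowest median of the macrophage and epithelial lists without either control array was 0.351 (highest camera adjusted p = 0.000226), and without the 3 arrays deposited at another scale the lower was 0.459 (4.22e-09), both at the preset correlation. Neither a single control array nor the scale would therefore account for these 2 lists, and fat was not tested. The macrophage and epithelial medians also lay above 0 on all 6 genistein arrays, though below those of every estradiol array. More macrophages per unit of RNA, or more RNA of these genes per cell, remain possible. Days since surgery, age or handling may add to the changes against control, since no untreated arrays of later days were analysed.

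Cholesterol synthesis genes were shifted down as a list with both treatments, with 4 and 0 of 15 genes passing over all genes, and the list did not pass with an estimated correlation (adjusted p = 0.0529 with estradiol and 0.0591 with genistein). A single control array might have caused this, but the median nearest to 0 without either control array was -0.253 (highest camera adjusted p = 0.0131 at the preset correlation). Days since surgery, age or handling could lower them as well as the treatments, and with 0 untreated arrays at days 2, 3 or 6 this cannot be told.

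Malat1 was higher with estradiol. RNA breakdown might raise a stable nuclear RNA, but with the ratio of 3' to 5' Gapdh signals in the model the change was 2.06 (limma, adjusted p = 0.00911). The scale of 3 arrays would not explain day 6, when no array was off scale and the change was 2.31 with a lower 95% bound of 1.43. A higher yield of nuclear RNA could raise other nuclear RNAs too. The median change of 4 of them was 0.133. Airn stood at 0.473 ± 0.144, Neat1 at 0.134 ± 0.24, Xist at 0.132 ± 0.274 and Meg3 at -0.0852 ± 0.133. All 4 lay below the Malat1 probe set that passed, but a smaller part from yield is not excluded. Whether the estradiol day 3 and day 6 arrays, set apart on the second principal component, shared a batch was not tested. A change in Malat1 itself remains possible, although only 1 of its 5 probe sets passed.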

How the results depend on the processing

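The tests of the values as deposited, without the 3 arrays at another scale, with that scale as a block and with the Gapdh ratio as a covariate were chosen only after the result was seen. With 2 arrays per group, and signals near the pseudocount for dim genes such as Slc2a4 in controls, single calls depend on the spread estimated from few arrays. Counts below are probe sets at limma's adjusted p of 0.05, E stands for estradiol and G for genistein, C for control, and the mean is over days. Where a value moved, the cause was not tested. Leaving out 1 array leaves a group with 1, which is assumed to vary like the other groups.

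With 1 array left out, E against C ranged from 1 to 312 at day 2, 0 to 184 at day 3, 0 to 367 at day 6 and 4 to 560 for the mean. G against C ranged from 0 to 287, 0 to 101, 0 to 151 and 1 to 335, and E against G from 1 to 16, 0 to 6, 0 to 67 and 62 to 321. Change over days of E ranged from 0 to 8, of G from 0 to 2, the interaction from 0 to 1, and the correlation of the treatments from 0.638 to 0.873, for which no values without an effect were simulated, so that a higher r does not mean closer agreement. For the mean, Cd8a ranged from -0.181 to 0.0596 with E and from -0.0560 to 0.184 with G, Rag1 from -0.0722 to 0.0950 with E, from -0.0636 to 0.0600 with G and from -0.0705 to 0.0967 for E against G, and Cd4 from -0.0690 to 0.192 for E against G.

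With a pseudocount of 1, G against C had 4, 2 and 2 at days 2, 3 and 6, E against G 1 at day 3 and 17 at day 6, and the interaction 1. With a pseudocount of 64, G against C had 0 at days 2 and 3 and 2 for the mean, and change over days of E 5. With no filter on low values, E against C had 4 at day 2, 44 at day 6 and 38 for the mean, G against C 0 at days 2 and 3 and 1 for the mean, E against G 125 for the mean, change over days of E 7 and the interaction 1. With the lowest 60% of probe sets left out, E against C had 3 at day 3, G against C 0 at each day and for the mean, E against G 0 at day 3 and change over days of E 0.

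With quantile normalization, E against G had 1 at day 3 and the interaction 1, the ribosomal protein list with G had a median of -0.00782 and Cd8a with G was -0.002609. With arrays centred on their median, E against G had 1 at day 3 and 15 at day 6, and Rag1 was -0.0170 with E, 0.0001345 with G and -0.0171 for E against G. The higher and lower counts became 8 and 3 for E at day 3. With eBayes without a trend, E against C had 7 at day 2, E against G 1 at day 3 and the interaction 1. With only the groups compared, E against C had 0, 1 and 27 at days 2, 3 and 6, G against C 0 at each day and 1 for the mean, E against G 5 at day 2 and 2 at day 6, and change over days of E 1. Without _x_at and _s_at probe sets the interaction had 1. Over all comparisons camera passed 198 list results at its preset correlation and 0 with estimated correlation, and fry, which need not pass the same ones, 127.

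With the replicate number as a block, G against C had 2 at day 3 and 2 at day 6, and E against G 1 at day 3 and 15 at day 6. The numbers did not pair the arrays, since over 21 pairs of groups the correlation of deviations ranged from -0.256 to 0.351 with a median of -0.00631.

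With the values as deposited, without rescaling, E against C had 92 (0 lower, median shift 0.28), 12809 (0 lower, shift 1.01), 29 and 4298 at days 2, 3, 6 and for the mean, and G against C 0 at day 3 and 3 for the mean. E against G had 43 (0 lower, shift 0.26), 13034 (1 lower, shift 1.01), 6 and 9262, change over days of E 12705 and the interaction 7951. The higher values follow from the scale of 3 arrays. Cd8a was 0.39 with E and 0.33 for E against G, Cdk1 0.0396 and 0.122, and for E against G Aurka was 0.0549, Oaz1 0.14, Cd8b1 0.17, Rps4x 0.22, Rpl8 0.21 and Ctss at day 3 0.33. Without the 3 arrays deposited at another scale, which leaves no array of E at day 3, E against C had 4 at day 2, 38 at day 6 and 26 for the mean, G against C 0 at each day and 1 for the mean, E against G 16 at day 6 and 41 for the mean, and change over days of E 0. Cd4 was -0.0004522 with E and -0.0341 for E against G. With the deposited scale as a block, E against C had 0 at day 3 and 14 for the mean, E against G 0, 19 and 32 at days 3 and 6 and for the mean, change over days of E 0, the correlation of the treatments was 0.541 and Cd4 was -0.10 with E and -0.24 for E against G. With the Gapdh 3' to 5' ratio as a covariate, E against C had 19 at day 3 and 183 for the mean, G against C 7, 2, 3 and 3, E against G 6, 1 and 0 at days 2, 3 and 6, Rag1 was 0.00339 with G and Cd4 -0.11 for E against G.

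Of the values of named genes, 1425 kept direction and side of the threshold with 1 array left out, 456 became weaker, 21 stronger and 16 turned. In the other settings these were 1433, 372, 25 and 20. Of list values, 348 held with 1 array left out and 2 became weaker, and in the other settings 244 held, 4 became weaker and 1 turned, besides 25 that became weaker with an estimated correlation.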

Other observations

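The genes and tests in this part were chosen only after the result was seen.

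Beside Trgv1, a probe set of Trgv4, another segment of the T cell receptor γ chain, rose with estradiol by 1.04 ± 0.144 against control (limma, adjusted p = 0.00524) and was 0.97 ± 0.102 above genistein, while the other Trgv4 probe set stood at 0.60 ± 0.154 (adjusted p = 0.0982). A second probe set of Il2ra, which marks early thymocytes, rose by 1.41 ± 0.170 (limma, adjusted p = 0.00355). Iglv1 and the joining chain Jchain rose at day 6 of estradiol by 1.72 ± 0.209 and 1.15 ± 0.198 against control (limma, adjusted p = 0.00211 and 0.0200). Jchain was also higher at day 6 of genistein, with a log2 level of 8.363 against 7.695 in controls and 8.845 with estradiol. For Iglv1 these levels were 6.493, 6.212 and 7.934. Igha had signals of 275 ± 18.7 in controls, and at day 6 of 152 ± 57.5 with estradiol and 436 ± 156 with genistein (SD, n = 2).

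Single probe sets of genes of fat synthesis, chosen after their values were seen and not tested as a group, passed between estradiol and genistein. They belonged to malic enzyme Me1 (1.51 ± 0.152, limma, adjusted p = 0.000395), fatty acid synthase Fasn (0.69 ± 0.116, adjusted p = 0.0107), Gpd1 (1.04 ± 0.172) and Thrsp (1.21 ± 0.274), while the other probe set of Me1, of Gpd1 and of Thrsp did not pass. Ucp1, the uncoupling protein of brown fat, varied widely within groups, with signals of 18.4 ± 8.70 in controls, 367 ± 250, 144 ± 100 and 79.2 ± 82.7 at days 2, 3 and 6 of estradiol, and 17.3 ± 8.20, 5.90 ± 3.39 and 129 ± 122 of genistein (SD, n = 2).

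Further lists were among the 17 of 34 that passed camera as higher with estradiol against control over the mean of days. Interferon response genes had a median of 0.22 over 26 (camera adjusted p = 0.000446; adjusted p = 0.275 with an estimated correlation), with 0 limma calls over all genes, and 3 higher and 1 lower adjusted over the list alone. MHC class I genes had 0.25 over 14 (camera adjusted p = 0.000416; adjusted p = 0.105 with an estimated correlation), with 0 calls over all genes and 3 higher adjusted over the list alone. Granulocyte markers had 0.67 over 6 (camera adjusted p = 0.000246; adjusted p = 0.116 with an estimated correlation), with 0 calls over all genes and 5 higher adjusted over the list alone.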
